A study of Mus musculus with 2 samples.

How the data were processed

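Single-cell RNA was measured by 3' droplet sequencing with unique molecular identifiers (UMIs, tags that count each captured transcript once) in CD45+ leukocytes sorted from B16 tumours, a transplanted mouse melanoma, 14 days after inoculation of female C57BL/6 mice aged 5 weeks. There were 2 libraries, 1 per genotype. The control library came from Foxp3Cre-YFP mice, which express Cre recombinase and a yellow fluorescent protein from the Foxp3 locus of regulatory T (Treg) cells. The other came from Nrp1L/L Foxp3Cre-YFP mice, in which Nrp1 is floxed so that Cre removes part of it in those cells. Per the labels, 2600 cells were loaded for each library on a GemCode instrument and the cDNA was amplified over 14 PCR cycles. Per the submitters' processing notes, reads were aligned to the mm10 mouse genome and counted with Cell Ranger 1.3. The deposited matrices hold UMI counts per gene and barcode, and all values were whole numbers. Both matrices list the same 27998 genes and only barcodes already called as cells.

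The control matrix held 1310 barcodes and 13042802 UMIs, with a median of 8079.5 UMIs and 1737 genes per barcode and a range of 3414 to 84144 UMIs. The Nrp1L/L matrix held 1301 barcodes and 8978610 UMIs, with a median of 5334 UMIs and 1323 genes and a range of 2659 to 42414 UMIs. Median depth was therefore 1.51-fold higher in the control library. The filter of at least 200 genes and at most 10% mitochondrial UMIs removed 0 barcodes. The highest mitochondrial share was 1.37% in the control and 1.65% in the Nrp1L/L library. Doublets were scored in each library alone with Scrublet, as built into scanpy 1.11.5, at an expected rate of 2%. Its own threshold was used where it called 0.5% to 10% of a library, and otherwise the highest 2% of scores were left out. It called 8 control barcodes (0.611%), which were left out. It called 3 Nrp1L/L barcodes (0.231%), so the highest-scoring 26 were left out there. This kept 1302 control and 1275 Nrp1L/L cells, 2577 of 2611.

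Cells were clustered jointly without batch correction, since genotype and library cannot be told apart. Counts were scaled to 10000 per cell and log-transformed, and 2500 variable genes (2000 within branches) gave 30 principal components (20 within branches). A graph of 15 nearest neighbours was partitioned by the Leiden method at resolution 1. Genes of the comparison lists, the cell cycle list included, were kept out of the clustering genes unless they were class markers. Mitochondrial and ribosomal genes, Xist, and variable, diversity and joining segments of T cell receptor and immunoglobulin genes were kept out as well, while every class marker found in at least 10 cells was added. Lymphoid and myeloid clusters were clustered again apart, and CD3+ cells not named CD8 T-like once more. Each marker was scaled to its highest cluster mean and averaged over the class's markers found in at least 10% of some cluster's cells, of which at least 3 were needed. In the first and lymphoid levels the highest score named a cluster if it reached 0.5, with 0.4 for NK cells and 0.3 for the CD3 genes of T cells. Myeloid clusters took their highest-scoring class. A cluster lost its name where another class had more markers among its 10 leading genes than its own class had, and a myeloid cluster whose CD3 genes reached 0.5 of their T cell level stayed unnamed. Names carry "-like" because they rest on transcripts alone. The marker lists, gene lists, rule for named genes, comparisons and first set of alternatives were chosen before the data were examined. The third clustering level, the score minimums and the rules that leave a cluster unnamed were settled after the data were examined. The share of cells with a cell cycle score above 0 was given with the number of cells within 0.05 of that limit.

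For each class with at least 30 cells in both libraries, UMIs were summed per library and scaled to CPM, counts in each 1000000 of the class total. Log2 ratios are Nrp1L/L over control. CPM carry exact Poisson intervals, log2 ratios exact conditional binomial intervals, shares of cells or UMIs exact Clopper-Pearson intervals and share differences Newcombe intervals, all at 95%. A share of 0 is given with the share that 3 counts would make as its upper limit, in place of the Clopper-Pearson limit. With 1 library per genotype no test of the genotype is possible, so no p-value is given, and the intervals cover counting error only. Where 1 side had 0 counts, a floor of 3 counts over the class gave a lower bound. Fixed gene lists were summarised over members with at least 20 UMIs over both libraries. Some genes belong to more than 1 list, so the list medians are not independent of each other. Each list was given its median log2 ratio with an interval from 1000 Poisson draws, the counts of members at least 1.5-fold higher or lower, and the percentile of its median among 10000 random lists matched on mean expression in 20 bins. Named genes were the 10 higher and 10 lower per main class whose interval bound nearest 0 was farthest from 0. They needed at least 50 UMIs and a UMI in at least 10% of the class's cells in the library with the higher level. Mitochondrial, ribosomal, Xist and antigen receptor segment genes were left out of that choice. Nrp1, Foxp3, Ifng, Srebf1, Fasn, Acaca, Scd1, Scd2, Arg1, Mrc1, Cxcl9, Gzmb and Pdcd1 were always reported. From each list, the pair of members with the most UMIs and the pair with the largest ratio were eligible as examples. Shares of cells with a UMI were also computed after thinning every cell to 1000 UMIs.

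Lists of dissociation stress, melanoma, erythroid, fibroblast and endothelial genes served as quality checks. Free RNA was estimated per class from transcripts the class should lack, Cd3d, Cd3e and Cd3g in myeloid classes and C1qa, C1qb and C1qc in lymphoid classes. The estimates ran from 0.883% to 3.07% of the library profile. Gene positions are from GENCODE M21 (GRCm38), which matched 27645 of the 27998 gene identifiers.

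The calculation was tested on simulated data, with Poisson counts drawn from the pooled profile of each class at the observed totals and 200 genes changed. These draws follow the same independent-count model as the intervals, so they check the calculation only. UMIs that clump within cells were not simulated, so the rates below need not hold for the data. Genes needed at least 50 UMIs. The intervals covered the true ratio for 95.7% of the unchanged genes at monocyte and macrophage totals (7115 genes simulated), 95.7% at CD8 T cell totals (7026 genes) and 95.8% at Treg totals (2802 genes). They excluded 0 for 94.0%, 95.5% and 85.1% of genes changed 2-fold, and for 68.7%, 74.6% and 52.2% of genes changed 1.5-fold. The alternatives tried were other cell filters, doublets kept, other resolutions, comparison lists kept among the clustering genes, each library clustered alone, classes from marker scores of each cell, and other scalings (TMM, median of ratios, totals without mitochondrial and ribosomal genes, mean over cells). Further ones were thinning to 1000 UMIs, leaving out cycling cells and list minimums of 5 and 50 UMIs. Subtraction of free RNA and keeping a stress-gene cluster among macrophage-like cells were added after seeing the data. Analyses ran in Python 3.11.15 with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, igraph 0.11.9 and matplotlib 3.10.9. Raw reads were not analysed here.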

Results

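The data are 2 single-cell libraries of CD45+ leukocytes from B16 melanomas, 1 from Foxp3Cre-YFP control mice and 1 from Nrp1L/L Foxp3Cre-YFP mice. There were no replicates, so genotype cannot be told apart from mouse, tumour or library, and each comparison below gives the size of a difference with no test. The control library held 1302 kept cells with 12912194 UMIs and the Nrp1L/L library 1275 kept cells with 8774789 UMIs. The series title sets the questions: what Treg cells do to the SREBP1-dependent metabolism of suppressive tumour macrophages, and whether interferon-gamma from CD8 T cells lies between them. SREBP1, encoded by Srebf1, is the transcription factor that switches on fatty acid synthesis.

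Nrp1 is the targeted gene. It encodes neuropilin-1, a co-receptor that many thymus-derived Treg cells carry, and Foxp3-driven Cre should disrupt it in Treg cells alone. Nrp1 (ENSMUSG00000025810, chromosome 8, 128358604 to 128503363, plus strand, GRCm38) was still counted in Treg-like cells of both libraries. Its level there was 87.9 CPM (65.2 to 116) from 50 UMIs in the control library. In the Nrp1L/L library it was 73.2 CPM (49.4 to 105) from 30 UMIs, a log2 ratio of -0.26 (-0.97 to 0.42). That ratio was -1.12 with each library clustered alone. After thinning to 1000 UMIs per cell the control gave 0 UMIs, so the value of 0.59 is a lower bound from the floor of 3 counts. The direction was not settled. A UMI was found in 18 of 57 control Treg-like cells (31.6%) and 10 of 63 Nrp1L/L ones (15.9%), at median depths of 7317 and 5044 UMIs. In NK-like cells, which should lack the gene, the shares were 0.862% and 0.833% at median depths of 6043 and 4137.5 UMIs. After every cell was thinned to 1000 UMIs, the Treg shares were 0 of 57, which allows up to 5.26%, and 4 of 63 (6.35%), against 0 of 116 (up to 2.59%) and 0 of 240 (up to 1.25%) in NK-like cells. Tags at the 3' end of a floxed gene can lie outside the deleted part, which the sources used here do not give, so these counts do not test the deletion. Foxp3 itself (ENSMUSG00000039521, chromosome X, 7573644 to 7595245) gave only 3 UMIs in the control and 5 in the Nrp1L/L library, and the Treg-like class therefore rests on Il2ra, Ikzf2, Ikzf4, Cd4 and CD3 genes. Nrp1 also stood lower in CD8 T-like cells, where Foxp3-driven Cre should be silent, at 56.6 CPM in the control and 23.1 CPM in the Nrp1L/L library (log2 -1.29, -1.70 to -0.90). In monocyte- or macrophage-like cells it stood at 61.6 and 57.4 CPM.

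The first comparison asks which leukocytes filled the tumours of each genotype. Monocytes and macrophages made up the largest named group in the control library, and lymphocytes filled most of the Nrp1L/L library. CD8 T cells and NK cells are the main killers of tumour cells and the main sources of interferon-gamma, and both held larger shares of the Nrp1L/L library. Treg-like cells held similar shares of the CD45+ cells in both. Conventional dendritic cells, which present tumour antigen to T cells, held a smaller share of the Nrp1L/L library.

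Monocyte- or macrophage-like cells were 39.7% of control cells (37.0 to 42.4, 517 cells) and 17.7% of Nrp1L/L cells (15.7 to 19.9, 226 cells), a difference of -22.0 percentage points (-25.3 to -18.6). Over the alternatives that difference ran from -29.8 to -18.6 points, so its size depends on processing. Monocyte-like cells went from 23.3% to 10.7% and macrophage-like cells from 16.4% to 6.98%, so macrophage-like cells were 41.4% and 39.4% of the pair. That split depends on processing: the monocyte-like difference ran from -20.7 to -7.82 points over the alternatives and the macrophage-like one from -17.3 to -9.09. CD8 T-like cells were 17.9% (15.8 to 20.1, 233 cells) and 30.7% (28.2 to 33.4, 392 cells), a difference of 12.8 points (9.56 to 16.1). NK-like cells were 8.91% and 18.8%, a difference of 9.91 points (7.27 to 12.6). Treg-like cells were 4.38% and 4.94%, a difference of 0.56 points (-1.08 to 2.22), or -2.37 with each library clustered alone. Among CD3+ cells, which were 30.6% of control and 57.4% of Nrp1L/L cells, the Treg-like share was 14.3% (11.0 to 18.1) and 8.61% (6.68 to 10.9). There were 4.09 CD8 T-like cells per Treg-like cell in the control and 6.22 in the Nrp1L/L library, and 0.451 and 1.73 per monocyte- or macrophage-like cell. CD4 T-like cells outside the Treg class were 1.31% and 3.14%, and plasmacytoid dendritic-like cells 1.84% and 1.02%. Conventional dendritic-like cells were 8.60% and 1.80%, a difference of -6.80 points (-8.55 to -5.14). CD3+ cells of no named class were 7.07% and 18.6%, a myeloid cluster left unnamed because its 10 leading genes held the plasma cell marker Sdc1 and no macrophage marker was 8.83% and 1.02%, and a cluster with both CD3 and myeloid genes was 1.31% and 0.235%. All these are shares of sorted, loaded cells and not cell numbers per tumour.

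**Figure D1:**
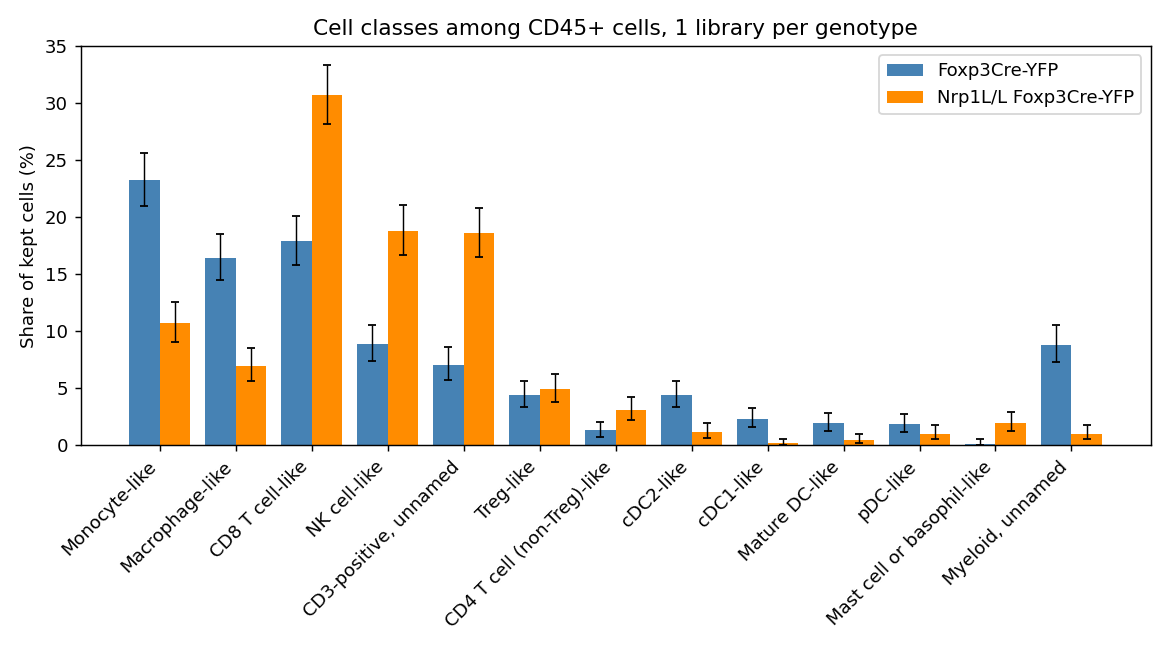
Share of kept CD45+ cells (vertical axis, percent) in each cell class for the control (Foxp3Cre-YFP) and Nrp1L/L libraries, bars with exact 95% intervals. Monocyte- and macrophage-like bars are taller in the control library, and CD8 T-, NK- and unnamed CD3+ bars are taller in the Nrp1L/L library.

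The next comparison looks at the monocytes and macrophages themselves and asks whether their interferon response and lipid metabolism differed between genotypes. Genes that interferon-gamma switches on stood higher across the Nrp1L/L cells, from the chemokines Cxcl9 and Cxcl10, which draw in T cells, to the guanylate-binding protein Gbp2 and the signalling brake Socs1. Genes of antigen presentation by MHC class I, some of them members of the interferon-gamma list as well, stood higher too. Genes of cholesterol synthesis, such as Fdps and Stard4, stood lower. The fatty acid synthesis genes Fasn, Scd2 and Elovl6 stood lower too, Fasn and Elovl6 on few UMIs. The median of the list they belong to lay inside the range of random lists. Srebf1 itself was near equal, within a wide counting interval. Spp1, Mrc1 and Arg1, genes of tumour-promoting macrophages, stood lower. The median of the list they belong to hardly moved in monocytes and macrophages together, but stood lower in monocyte-like cells alone.

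The clusters behind this class differed between libraries. Control cells were spread over 7 clusters, and the largest shares lay in a macrophage-like cluster led by Dct, C1qa, Pf4, Gas6, Mt2 and Igfbp4 (19.5% of the class, against 6.64%) and in monocyte-like clusters led by Cxcl3, Cxcl1, Slpi and Spp1 (19.3%, against 5.31%) and by Lyz1, Ly6i and Il1b (18.2%, against 9.73%). Nrp1L/L cells lay mainly in a monocyte-like cluster that Cxcl10, Gbp2 and Cxcl9 helped to lead (34.5%, against 10.8%) and a macrophage-like cluster led by Ccl8, Il18bp and Ms4a7 (27.4%, against 11.0%). Median depths were close, at 8765 and 8149.5 UMIs. The median log2 ratio of all 9035 genes measured in this class was -0.13, and median-of-ratios scaling moved it by 0.10. In macrophage-like cells alone the median was -0.18, and that scaling moved it by 0.12 and TMM by 0.11.

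The interferon-gamma response list had a median log2 ratio of 1.296 (1.10 to 1.37), at percentile 100 of random lists, and 25 of its 28 measured members stood at least 1.5-fold higher and 0 at least 1.5-fold lower. Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079) stood at 58.7 CPM in the control and 522 CPM in the Nrp1L/L library, a log2 ratio of 3.15 (2.97 to 3.34). Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889) stood at 447 and 1736 CPM (1.96, 1.88 to 2.03). The most abundant member, Psmb8, stood at 1126 and 1699 CPM. Type I interferon genes, many of which interferon-gamma also induces, had a median of 1.03 (0.97 to 1.12), with 17 of 21 members at least 1.5-fold higher, Isg15 among them at 1072 and 2190 CPM. MHC class I genes had a median of 0.82 with 11 of 13 members at least 1.5-fold higher. Of these, Tap1 stood at 201 and 404 CPM. Tap1, Tap2, Psmb8 and Psmb9 are in both this list and the interferon-gamma list, so the medians are not separate results. MHC class II genes had a median of 0.45 (0.42 to 0.49), with 8 of 8 members above 0 and none at least 1.5-fold higher, but 0.11 without cycling cells. That median was 1.01 in macrophage-like cells (0.37 without cycling cells) and -0.04 in monocyte-like cells, where it ran from -0.48 with the comparison lists among the clustering genes to 0.14 at a resolution of 0.5. The interferon-gamma list stood higher in both, at 1.17 and 1.26.

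Of 10 measured SREBP1 targets of fatty acid synthesis, 5 stood at least 1.5-fold lower and 1 higher, with a median of -0.42 (-0.69 to -0.21) at percentile 14.4 of random lists. In macrophage-like cells alone the median was -0.19 (-0.59 to 0.13), with 2 of 9 members lower and 1 higher. In monocyte-like cells alone it was -0.31 (-0.74 to -0.07), with 3 of 8 lower and 1 higher. For both together, the median was -0.11 when only members with at least 50 UMIs counted and -0.77 at a clustering resolution of 0.5. Melanoma genes, which belong to tumour cells, stood lower in the same class too (229 and 27.4 CPM, a median of -2.86), and whether RNA of tumour cells carries part of the SREBP1, SREBP2 or cell cycle values was not tested. The SREBP1 targets were rare. Fasn (ENSMUSG00000025153, chromosome 11, 120805846 to 120824547) gave 38 control and 3 Nrp1L/L UMIs, a log2 ratio of -2.22 (-4.56 to -0.57), and Elovl6 gave 43 and 2 UMIs (-2.99, -6.08 to -1.05). Scd2 stood 2.60-fold lower, and Scd1 with 17 and 1 UMIs and Acaca with 12 and 4 UMIs were too rare to compare. Srebf1 (ENSMUSG00000020538, chromosome 11, 60199089 to 60222581) stood at 17.7 and 17.6 CPM, a ratio of 0.992. Its level in this class was not resolved more finely than the interval of the log2 ratio, -0.62 to 0.57.

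SREBP2 targets of cholesterol synthesis and uptake had a median of -0.69 (-0.81 to -0.36), at percentile 0 of random lists, with 9 of 18 members at least 1.5-fold lower and 1 higher. Fdps stood at 201 and 109 CPM (-0.89), Stard4 at 29.2 and 11.4 CPM (-1.36), and the abundant Ebp slightly higher (0.19). Classes from the marker scores of each cell gave a smaller median of -0.31. Lipid uptake and storage genes had a median of -0.36 (-0.51 to -0.22), with 6 of 18 members at least 1.5-fold lower, Gpnmb among them (-1.95), and 3 higher, such as Dgat2. Apoe stood at 3477 and 2442 CPM. The lipid uptake and storage median was -0.19 (-0.43 to 0.12) in macrophage-like cells alone and -0.21 (-0.80 to -0.11) in monocyte-like cells alone. Fatty acid oxidation genes had a median of -0.44 (-0.54 to -0.08) with 4 of 17 lower, Hadh and Etfb among them, and thinning brought it to -0.039. Glycolysis and hypoxia genes had a median of -0.25, with Ldha at -0.30 and Egln3 at -1.41. All 32 oxidative phosphorylation genes lay within 1.5-fold, at a median of -0.11.

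The list of alternatively activated and tumour-promoting macrophages had a median of -0.12 (-0.29 to -0.01), inside the range of random lists at percentile 36.3, with 5 of 17 members at least 1.5-fold lower and 1 higher. Spp1 stood at 1767 and 508 CPM (-1.80), Mrc1 at 76.4 and 28.5 CPM (-1.43), Cbr2 at 56.6 and 12.4 CPM, and Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484) at 1257 and 862 CPM (-0.54, -0.62 to -0.47). Classically activated macrophage genes, with Cxcl9 and Cxcl10 again among them, had a median of 0.42 with 5 of 14 higher. Cd40 stood at 49.4 and 201 CPM, while Il1b was near equal (-0.09). Alternative activation alone was at -0.29 (-0.37 to -0.15) in monocyte-like cells, with 7 of 15 lower and 1 higher. In macrophage-like cells it was at -0.01 (-0.28 to 0.10). Classical activation was at 0.13 (-0.10 to 0.22) in monocyte-like cells, with 3 of 14 higher and 4 lower. In macrophage-like cells it was at 0.80 (0.70 to 1.05), with 9 of 13 higher. Cell cycle genes had the lowest median of the comparison lists, -1.58 (-1.81 to -1.39), with 25 of 29 members at least 1.5-fold lower. That median was -1.52 in macrophage-like and -0.024 in monocyte-like cells, and -0.17 in the pair without cycling cells. The score called 43.9% of control and 19.1% of Nrp1L/L macrophage-like cells cycling, with 25 and 15 cells within 0.05 of the limit. Chemokine genes had a median of -0.27, with Ccl2 at 6349 and 5565 CPM. Complement and lysosome genes had a median of -0.08, which became 0.0055 and 0.025 under TMM and median-of-ratios scaling and 0.13 without cycling cells. Ctss stood higher (0.57) and Ctsl lower (-1.50). Lists of lymphocyte genes were also computed here. Their medians were 0.59 for cytotoxic, 0.32 for inhibitory receptor, 0.69 for memory, 0.18 for activated Treg and 0.30 for T helper 1 genes, from transcripts that include RNA of other cells. After thinning, inhibitory receptor (-0.39), activated Treg (-0.24) and T helper 1 genes (-0.20) lay below 0, and with classes from marker scores of each cell the cytotoxic median was 2.15. Gzmb, for example, stood at 18.3 and 40.9 CPM, and Pdcd1, with 19 and 11 UMIs, at 3.62 and 5.69 CPM.

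Among single genes, the 10 with the clearest higher values in the Nrp1L/L cells were interferon-inducible for the most part: Cxcl9, Gbp2b, Serpina3f, Fam26f, Tgtp1, Serpina3g, Pdcd1lg2, Socs1, Gbp2 and Cxcl10. Their log2 ratios ran from 1.96 for Cxcl10 to 3.54 for Gbp2b. Serpina3f, Serpina3g, Tgtp1 and Gbp2b have close copies in the genome, so their counts are less certain. Pdcd1lg2, which encodes the PD-1 ligand PD-L2, stood at 6.48 and 41.9 CPM. The 10 clearest lower genes were Cxcl3, Cxcl1, Pf4, Npl, Mt2, Syngr1, Gas6, Igfbp4, Uck2 and Dab2. Cxcl3 and Cxcl1, chemokines for neutrophils, went from 398 and 150 CPM in the control to 3 and 2 UMIs, and Pf4 from 1467 to 144 CPM (-3.35). Cxcl3, Cxcl1, Pf4, Mt2, Syngr1, Gas6 and Igfbp4 are among the genes that lead the control-rich clusters.

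For CD8 T cells the question is whether they made more interferon-gamma and looked more cytotoxic in the Nrp1L/L tumours. Ifng, the chemokines Ccl3, Ccl4 and Ccl5 and the granule protease Gzmb stood higher in these cells. Granzymes split into those that stood higher (Gzma, Gzmb, Gzmk) and those that stood lower (Gzmc, Gzmf). The inhibitory receptors Lag3, Ctla4 and Havcr2 stood higher as well, while Pdcd1 differed little in the main setting. Type I interferon genes stood higher and cholesterol synthesis genes lower.

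Control CD8 T-like cells lay mainly in a cycling cluster led by Gzmf, Ube2c and Top2a (60.5%, against 26.0%), and the largest share of Nrp1L/L ones in a cluster led by Ccl5, Cxcr6, Lag3, Gzmk and Ifng (48.5%, against 10.7%). Their median depths were 10824 and 6493 UMIs. Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892) stood at 252 CPM (758 UMIs) and 660 CPM (2205 UMIs), a log2 ratio of 1.39 (1.27 to 1.51). The cytotoxic and effector list had a median of 1.00 (0.74 to 1.03) with 12 of 22 members at least 1.5-fold higher and 4 lower, and its mean of -0.02 differed in sign because of Gzmf and Gzmc. Gzmb stood at 1923 and 4177 CPM (1.12, 1.07 to 1.16), Nkg7 at log2 0.96 and Prf1 at 46.9 and 53.9 CPM. Gzmf gave 845 and 1 UMIs, and Gzmc stood at 634 and 19.5 CPM (-5.03, or -1.93 with each library clustered alone and -6.26 without cycling cells). Inhibitory receptor and exhaustion genes had a median of 0.39, with 9 of 19 higher. Lag3 stood at 220 and 617 CPM and Pdcd1 at 431 and 531 CPM. The log2 ratio of Pdcd1 ran from 0.22 to 0.93 over the alternatives. Naive and memory genes had a median of 0.50, with Il7r at 1.39, but -0.33 when each library was clustered alone and -0.27 without cycling cells. Cell cycle genes had a median of -0.33 (-0.38 to -0.26). The score called 62.2% and 40.6% of these cells cycling, with 35 and 72 cells within 0.05 of the limit.

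The interferon-gamma response list had a median of 0.84 (0.63 to 0.94) in CD8 T-like cells, with 14 of 23 members at least 1.5-fold higher. The type I list had a median of 1.47 (1.22 to 1.62), with 17 of 20 members higher, Isg15 at 75.8 and 257 CPM among them. Over the alternatives that median ran from 0.82, without cycling cells, to 1.88. MHC class I genes had a median of 0.60. MHC class II genes, foreign to mouse CD8 T cells, had a median of -0.88, which became 0.53 with doublets kept and 0.65 without cycling cells. SREBP2 targets had a median of -0.76 (-0.95 to -0.51) with 12 of 19 members lower, Fdps among them, and -1.68 after thinning. SREBP1 targets had a median of 0.00, which was -0.077 without mitochondrial and ribosomal genes in the total and -0.18 when every cell weighed the same, although Fasn (-1.41) and Scd2 (-1.18, or -2.75 after thinning and -0.26 without cycling cells) stood lower. Srebf1 was near equal (-0.10, -0.68 to 0.49), but -1.49 after thinning, and Acaca (-0.87, -1.94 to 0.15) and Scd1 with 6 and 12 UMIs were rare. Lipid uptake genes had a median of 0.72, or -0.036 when members with 5 UMIs counted. Medians were -0.07 for fatty acid oxidation, -0.24 for oxidative phosphorylation and -0.25 for glycolysis, the last 0.040 without cycling cells. They were 0.43 for alternative activation (-0.13 to 0.81, and -0.42 with classes from marker scores of each cell), 0.72 for classical activation, 0.22 for complement, 0.34 for activated Treg and 0.30 for T helper 1 genes. The chemokine list had a median of -0.83, which ran over the alternatives from -2.16 to -0.050, the latter after thinning. Of its 14 measured members, 10 stood lower. Of these, Cxcl2 stood at 74.2 and 8.98 CPM here and up to 5807 CPM in monocyte-like cells. Arg1 stood at 11.0 and 5.09 CPM, and Mrc1 and Cxcl9 gave a few UMIs each; how much of these genes is free RNA was not tested.

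The 10 clearest higher genes in CD8 T-like cells were BC094916, Gbp2, Ccl5, Oxsr1, 1700020L24Rik, Ccl3, Ccl4, Fam65b, Ifi27l2a and Frat2. Ccl5 stood at 3078 and 13541 CPM (2.14), Ccl3 at 557 and 2085 CPM, and Ccl4 at 1064 and 3711 CPM. The 10 clearest lower were Gzmf, Gzmc, Ccdc184, Cd70, Enpp2, Tmem158, Cxcl2, Utf1, Tff1 and Pkp4. Cd70, a costimulatory ligand, gave 58 and 2 UMIs.

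The source of Ifng transcripts is the next comparison, since the series title points to CD8 T cells. CD8 T-like cells held most Ifng transcripts in both libraries, and NK-like and CD4 T-like cells held most of the rest. The Nrp1L/L library held more Ifng transcripts in all. After every cell was thinned to the same depth, the CD8 T-like share was smaller in both libraries.

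All kept cells together gave 1052 Ifng UMIs (81.5 CPM) in the control and 3133 (357 CPM) in the Nrp1L/L library. CD8 T-like cells held 72.1% (69.2 to 74.7) and 70.4% (68.7 to 72.0) of them. NK-like cells held 13.5% and 9.06%, CD4 T-like cells 4.94% and 11.5%, unnamed CD3+ cells 3.14% and 6.42%, and Treg-like cells 4.09% and 1.82%. NK-like cells stood at 145 and 245 CPM (1.22 and 1.18 UMIs per cell), and CD4 T-like cells at 328 and 1155 CPM from 17 and 40 cells. An Ifng UMI was found in 50.2% and 62.2% of CD8 T-like cells at median depths of 10824 and 6493 UMIs. Monocyte- or macrophage-like cells, which should lack it, gave 0.387% and 5.75% at 8765 and 8149.5 UMIs. After thinning to 1000 UMIs, the CD8 shares were 14.2% (9.95 to 19.3) and 28.8% (24.4 to 33.6), against 0 of 517 (up to 0.58%) and 3 of 226 (1.33%) in monocyte- or macrophage-like cells. The depth gap between the libraries thus runs against the higher Nrp1L/L share. Of all Ifng UMIs left after thinning, CD8 T-like cells held 50.6% in the control and 59.8% in the Nrp1L/L library.

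**Figure D2:**
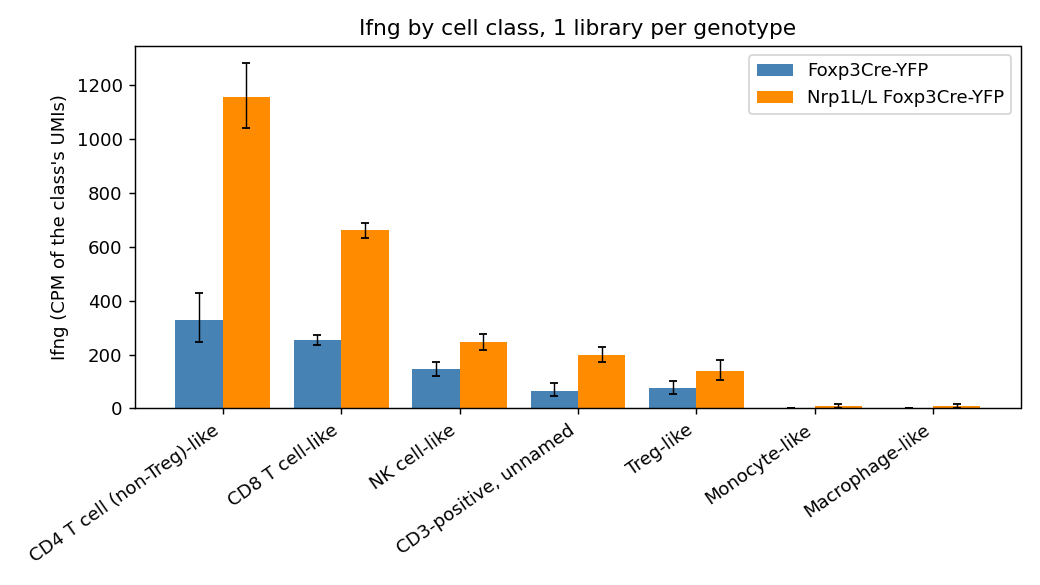
Ifng level in each cell class (CPM, bars with exact Poisson 95% intervals) in the control and Nrp1L/L libraries. CD4 T- and CD8 T-like cells of the Nrp1L/L library stand highest, at 1155 and 660 CPM. In the control and Nrp1L/L libraries, monocyte-like cells stand at 0.396 and 7.36 CPM and macrophage-like cells at 0.367 and 7.09 CPM.

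Treg cells are where the genotypes differ by design, and the question is whether the Nrp1L/L ones carried T helper 1 genes or lost genes of Treg function. Treg effector genes such as Gzmb, Areg, Tnfrsf4 and Ctla4 stood higher in the Nrp1L/L library, not lower. Runx3 stood higher too, and so did Ifng except after thinning, where it was near equal. The interferon-gamma receptor gene Ifngr1 differed little, and so did Pdcd1 in the main setting. Interferon-inducible genes stood higher, as in the other classes.

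The class held 57 and 63 cells, of which 50.9% and 82.5% lay in a cluster led by Areg, Tnfrsf4 and Ctla4 and the rest in a deeper cluster led by Tnfrsf4, Penk and Tyms. Activated Treg genes had a median of 0.39 (0.25 to 0.66) with 10 of 22 members at least 1.5-fold higher and 2 lower. Gzmb stood at 619 and 2092 CPM (1.76), Areg at 172 and 513 CPM (1.57), Tnfrsf4 at 1847 and 3139 CPM, and Ctla4 at log2 0.72. T helper 1 genes had a median of 0.38 (0.10 to 0.61) with 5 of 12 higher and 0 lower, but -0.10 after thinning to 1000 UMIs. Ifng stood at 75.6 and 139 CPM (43 and 57 UMIs; 0.88, 0.28 to 1.49), a log2 ratio that was 0.026 after thinning, 0.23 with each library clustered alone and 2.59 with doublets kept. Runx3 stood at log2 1.51, Pdcd1 at 446 and 381 CPM (-0.23, -0.53 to 0.06) and Ifngr1 at -0.02. The log2 ratio of Pdcd1 ran from -0.86 to 0.18 over the alternatives. An Ifng UMI was found in 21.1% and 30.2% of Treg-like cells, and after thinning in 7.02% and 9.52%. Dissociation stress genes, a quality list that marks handling, had a median of 0.54 (0.36 to 0.64) in the same cells, above those of the activated Treg and T helper 1 lists.

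Interferon-gamma response genes had a median of 0.56 in Treg-like cells, with 10 of 20 higher, Iigp1 and Gbp4 (1.58) among them, type I genes 0.98 with 9 of 11 higher, and MHC class I genes 0.45. Cytotoxic genes had a median of 0.85 with 10 of 14 higher and memory genes 0.83 with 5 of 7 higher. Cell cycle genes had a median of -0.42, which ran over the alternatives from -1.37 to 0.14, the latter with the comparison lists among the clustering genes. SREBP2 targets had a median of -0.75 with 7 of 13 lower, Stard4 (-1.72) among them, but -0.14 with the comparison lists among the clustering genes and -1.25 at a resolution of 0.5. Only 5 SREBP1 targets were measured (0.59, -0.09 to 1.24), Srebf1 with 11 and 8 UMIs and Fasn with 8 and 1 were rare, and Scd2, with 13 and 0 UMIs, stood at least 3.12-fold lower. Acaca with 3 and 0, Scd1 and Mrc1 with 2 and 0, Cxcl9 with 0 and 1, and Arg1 with 6 and 3 UMIs were too rare for a ratio. Medians were -0.50 for fatty acid oxidation, -0.19 for oxidative phosphorylation, 0.12 for glycolysis, -0.32 for lipid uptake, 0.22 for inhibitory receptors and 0.32 for complement genes. Medians of 0.67 for alternative activation, 0.47 for classical activation and 0.47 for chemokines rest on 5, 6 and 10 genes. The first was -0.17 at a resolution of 2, the second -0.31 with doublets kept, and the last -0.21 when every cell weighed the same. Lipid uptake became 0.11 with each library clustered alone and glycolysis -0.15 at a resolution of 0.5. MHC class II genes had a median of -2.51.

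The clearest higher genes in Treg-like cells were Oxsr1, Ccl4, Ifit3, Spp1, Ly6c2, Ccl3, Gzmb, Ipcef1, Ifit1 and Havcr2. Ccl4 stood at 392 and 2038 CPM (2.38), Oxsr1 gave 5 and 49 UMIs (3.77, but 0.085 with each library clustered alone), and the copy Ifit3b makes Ifit3 counts less certain. Spp1 and Ly6c2, myeloid genes at 4548 CPM in the unnamed myeloid cluster and 8862 CPM in plasmacytoid dendritic-like cells, reversed to -2.35 for Spp1 at a resolution of 2 and to -0.29 for Ly6c2 with the comparison lists among the clustering genes. The clearest lower genes were H2-Eb1, H2-Ab1, H2-Aa, Cxcl2, Cd83, Ttll12, Ctla2b, B3gat3, Wasf2 and Ccar1. H2-Eb1, H2-Ab1 and H2-Aa, at 12.2 to 232 CPM here, stood at 11685 to 17806 CPM in cDC2-like cells. Ctla2b, which has a close copy in Ctla2a, became 0.27 after thinning, and H2-Aa 0.57 at a resolution of 2.

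**Figure D3:**
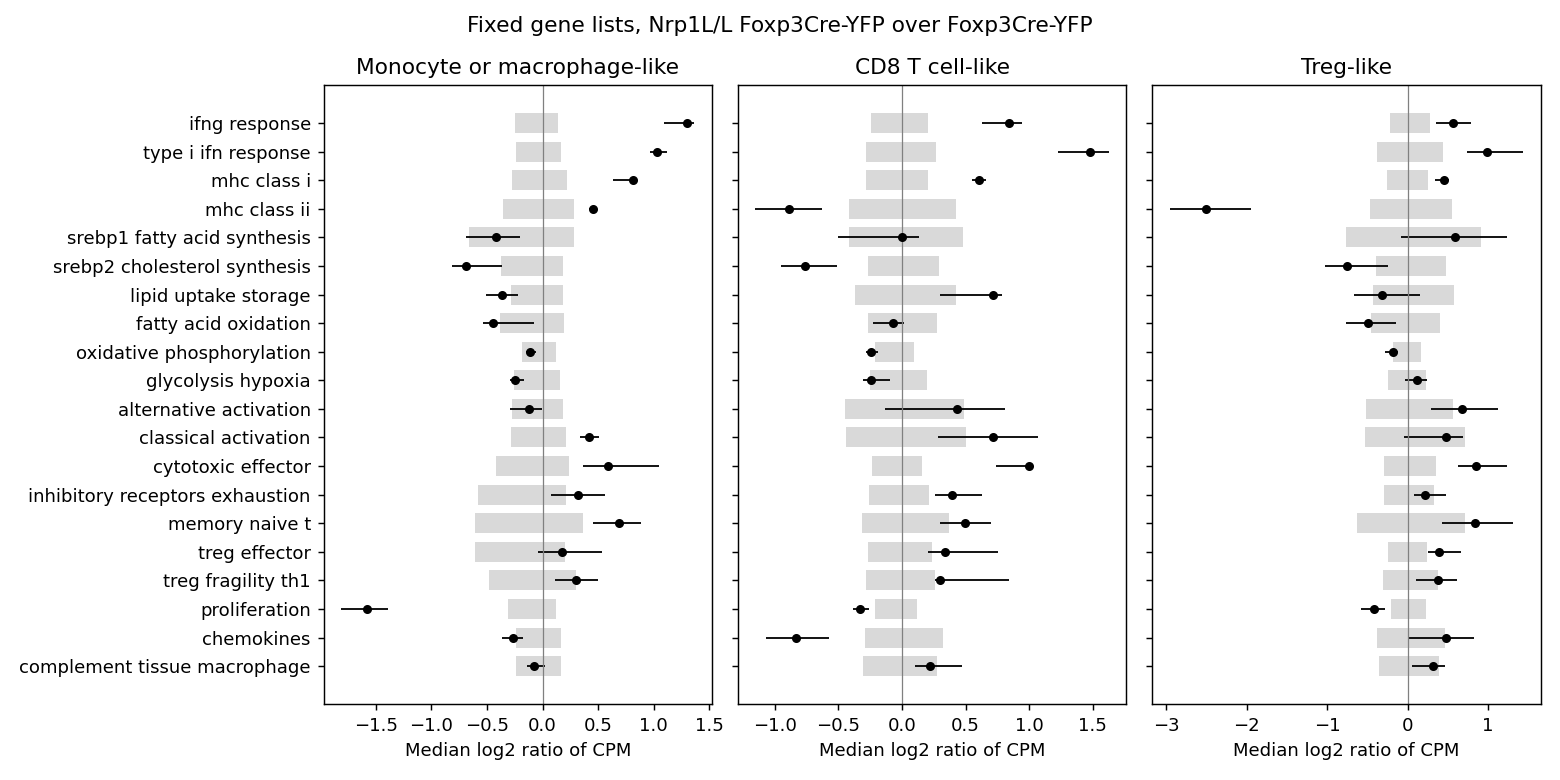
Median log2 ratio (Nrp1L/L over control) of each gene list in monocyte- or macrophage-like, CD8 T-like and Treg-like cells, points with 95% counting intervals and grey bars for the 95% range of random lists. Interferon lists lie to the right of the grey bars and SREBP2 targets to the left in all 3 panels.

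Other classes address whether interferon-inducible genes stood higher beyond the cells the title names. They did in both further classes with enough cells. NK-like cells had a median of 0.67 for the interferon-gamma list (13 of 22 members at least 1.5-fold higher), 1.34 for type I genes (16 of 19) and 0.49 for MHC class I genes. Dissociation stress genes stood higher in NK-like cells too, close to the interferon-gamma list, with a median of 0.64 (0.46 to 0.82) and 9 of 17 members at least 1.5-fold higher. Unnamed CD3+ cells had 0.45 (10 of 23), 0.78 (14 of 20) and 0.32. MHC class II medians were -1.46 and -0.996, in cells that should lack these genes.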

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

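Tests of the MHC class II genes were chosen after the difference between classes was seen, with their predictions written before their own values were known. None of the differences between classes given here was tested.

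MHC class II genes differed in direction between classes. These genes present antigen to CD4 T cells and belong to macrophages, monocytes and dendritic cells, not to mouse T cells. The list median in CD8 T-like cells lay -1.34 log2 units from that in monocyte- or macrophage-like cells, and the median in Treg-like cells lay -2.96 units from it, because the list stood higher in the macrophage-like cells of the Nrp1L/L library (1.01; monocyte-like cells -0.04) and lower in its T cells. H2-Aa, H2-Ab1 and H2-Eb1 together stood at 452 and 217 CPM in control and Nrp1L/L CD8 T-like cells, 589 and 61.0 CPM in Treg-like cells, and 264 and 83.6 CPM in NK-like cells.

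Free RNA alone should give these 3 classes of the control library a like level. The highest was 2.23-fold the lowest (1.89 to 2.63), above the 1.5-fold bound set beforehand. That interval counts UMIs as independent, while in Treg-like cells, the highest class, 2 cells held 74.9% of them. The ratio thus rests largely on those cells, and the test cannot decide whether free RNA gives the level of the others. A few cells may hold most of the transcripts: 10 of 233 control CD8 T-like cells had 10 or more such UMIs and held 73.8% of them (71.4 to 76.1). In Treg-like cells 2 of 57 control cells held 74.9% and 0 of 63 Nrp1L/L cells reached that number, and in NK-like cells 7 of 116 held 43.6% and 0 of 240 reached it. The CD8 T-like median became 0.53 with doublets kept and 0.65 without cycling cells, which left out 145 of 233 control and 159 of 392 Nrp1L/L cells, and the cause of these reversals was not tested. Doublet removal was unequal, with 8 control and 26 Nrp1L/L barcodes left out by different rules. Whether this accounts for the lower Nrp1L/L values was not tested. Whether the cells with 10 or more such UMIs are doublets with myeloid cells or T cells that carry MHC class II was not tested either. The genotype cannot be told apart from the library.

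The other differences in direction concern gene lists with few measured members in T cells. Alternative activation genes had a median 0.79 log2 units higher in Treg-like than in monocyte- or macrophage-like cells, on 5 genes in Treg-like cells led by Spp1. Chemokine genes had a Treg-like median 0.74 units above the myeloid one and 1.304 units above the CD8 T-like one. Ccl3 and Ccl4 stood higher in both T cell classes, and Cxcl2, a myeloid chemokine, stood lower in both. Lipid uptake and storage genes had a CD8 T-like median 1.08 units above the myeloid one, on 7 genes in CD8 T-like cells, with Lgals3 and Ctsd higher and Fabp5 lower. No explanation of these 4 differences was tested.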

How the results depend on the processing

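No paired analysis was possible because each genotype has 1 library. The 13 main results were recomputed under up to 18 settings each. This gave 171 values, of which 136 stayed within the counting interval, 34 left it and 1 reversed. All 3316 values, single genes and lists included, split into 2770, 514 and 32. All barcodes and the stricter cell filter changed nothing beyond the interval, because they remove 0 and 1 barcodes. Over all settings the interferon-gamma list in monocyte- or macrophage-like cells ran from 1.05 to 1.40, its SREBP2 targets from -0.74 to -0.31, the CD8 T-like share difference from 9.95 to 13.9 points and the NK-like one from 8.93 to 10.1. Unless a reason is given, the cause was not tested.

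With doublets kept, Ifng in CD8 T-like cells had a log2 ratio of 1.25 and these cells held 68.4% of Nrp1L/L Ifng UMIs. MHC class II in CD8 T-like cells became 0.53 and chemokines in Treg-like cells -0.23, and Ifng in Treg-like cells moved to 2.59.

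At resolution 0.5 the monocyte- or macrophage-like share difference was -29.8 points and the Treg-like one 2.55, SREBP1 targets were at -0.77, cytotoxic genes in CD8 T-like cells at 1.06, T helper 1 genes in Treg-like cells at 0.62, and CD8 T-like cells held 72.8% of Nrp1L/L Ifng. At resolution 2 the interferon-gamma list was at 1.38, Ifng in CD8 T-like cells at 1.24 and their Ifng shares 67.4% and 67.3%. There, alternative activation (-0.17), H2-Aa (0.57) and Spp1 (-2.35) in Treg-like cells and lipid uptake (0.23) and chemokines (0.16) in monocyte-like cells reversed.

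With the comparison lists among the clustering genes, the interferon-gamma list was at 1.37 and the CD8 T-like share of Nrp1L/L Ifng 72.2%. Cell cycle genes (0.14), Ly6c2 (-0.29) and Spp1 (-3.17) in Treg-like cells and lipid uptake in monocyte-like cells (0.25) reversed. With each library clustered alone, the share differences were -29.6 points for monocyte- or macrophage-like and -2.37 for Treg-like cells, Nrp1 in Treg-like cells was at -1.12, Ifng there at 0.23, Gzmc in CD8 T-like cells at -1.93, and the Ifng share was 76.4%. Memory genes in CD8 T-like cells (-0.33) and oxidative phosphorylation in monocyte-like cells (0.027) reversed. With classes from marker scores of each cell, the monocyte- or macrophage-like difference was -27.4 points and the Ifng share 67.3%. Alternative activation in CD8 T-like cells, whose interval of -0.13 to 0.81 includes 0, was at -0.42. Complement (-0.059) and Cxcl9 (-0.81) in CD8 T-like cells and oxidative phosphorylation in macrophage-like cells (0.064) reversed.

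Scaling moved the interferon-gamma list to 1.38 (TMM) and 1.40 (median of ratios), and oxidative phosphorylation in macrophage-like cells to 0.0087 and 0.024, as the shift of all genes there would. With every cell weighing the same, Ifng in CD8 T-like cells was at 1.59 and chemokines in Treg-like cells at -0.21.

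After thinning to 1000 UMIs, which leaves fewer counts, Ifng in CD8 T-like cells was at 1.70, Nrp1 in Treg-like cells at 0.59, Ifng in Treg-like cells at 0.026, and the CD8 T-like shares of Ifng were 50.6% and 59.8%. T helper 1 genes in Treg-like cells reversed to -0.10, and so did Ctla2b there (0.27), inhibitory receptor (-0.39) and T helper 1 genes (-0.20) in monocyte- or macrophage-like cells, fatty acid oxidation in macrophage-like cells (0.20) and alternative activation in monocyte-like cells (0.036).

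Without cycling cells, the interferon-gamma list was at 1.05, alternative activation at -0.30 and cytotoxic genes in CD8 T-like cells at 0.74. Inhibitory receptors in monocyte- or macrophage-like cells (-0.083), MHC class II (0.65), glycolysis (0.040) and memory genes (-0.27) in CD8 T-like cells and oxidative phosphorylation in macrophage-like cells (0.0077) reversed. With list members of at least 50 UMIs, SREBP1 targets were at -0.11 and cytotoxic genes at 1.04, and with at least 5, lipid uptake in CD8 T-like cells (-0.036) and chemokines in Treg-like cells (-0.13) reversed, on other sets of genes by construction.

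Some values whose counting interval includes 0 also changed sign. In Treg-like cells they included classical activation (-0.31 with doublets kept), lipid uptake, glycolysis and Pdcd1 (0.18 with doublets kept). In monocyte- or macrophage-like cells they included activated Treg genes, complement, Nrp1 (0.71 after thinning) and Pdcd1 (-0.43 at resolution 2). Cell cycle genes in that class kept their sign but came to -0.17 without cycling cells, as that alternative would by construction.

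Fatty acid oxidation in Treg-like cells came to -0.087 with doublets kept and Arg1 in monocyte- or macrophage-like cells to -0.20 with the comparison lists among the clustering genes. Activated Treg genes in Treg-like cells ran from 0.18 at resolution 0.5 to 1.10 with each library clustered alone.

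Keeping the stress-gene cluster, an alternative chosen after seeing the data, gave a monocyte- or macrophage-like share difference of -29.8 points and SREBP1 targets at -0.77, since it adds that cluster's cells. Subtraction of free RNA, also chosen after seeing the data, left the list medians and gene ratios among the main results within their intervals. The shares of cells and of Ifng UMIs were not recomputed under it. Depth limits the rare genes: only 5 SREBP1 targets were measured in Treg-like cells, and Scd1 and Acaca were too rare to compare in monocyte- or macrophage-like cells.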

Other observations

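Dendritic cells prime T cells, and most types of them held smaller shares of the Nrp1L/L library. cDC1-like cells, the type that presents tumour antigen to CD8 T cells, gave 30 control and 2 Nrp1L/L cells (2.30% and 0.157%), cDC2-like cells 57 and 15 (4.38% and 1.18%), and mature dendritic-like cells 25 and 6 (1.92% and 0.471%). Plasmacytoid dendritic-like cells gave 24 and 13, with an interval of the difference in share, -1.80 to 0.11 points, that includes 0. Basophil-like cells, named by Mcpt8, Cyp11a1 and Gata2, ran the other way with 2 and 25 cells (0.154% and 1.96%). Among unnamed CD3+ cells, a cluster led by Il17a and Cd163l1, genes of interleukin-17-making gamma-delta T cells, gave 12 and 21 cells. NK-like cells, which held Gzmc and Gzme in a cluster with 22.4% of control and 2.5% of Nrp1L/L cells of that class, had lower glycolysis genes in the Nrp1L/L library, with a median of -0.80 and 12 of 19 members at least 1.5-fold lower. Monocyte-like cells had lower glycolysis genes too (-0.52, 8 of 22), whereas macrophage-like cells did not (0.02, or -0.059 with mitochondrial and ribosomal genes out of the total and -0.25 with the unnamed myeloid cluster kept among them).

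The granzyme genes on chromosome 14 split in CD8 T-like cells. Gzmb stood higher, while Gzmc, Gzmf and, chosen after their values were seen, Gzmd (462 and 4 UMIs) and Gzme (478 and 14 UMIs) stood lower. The copies of this family are alike, so counts may pass between Gzmc, Gzmd, Gzme and Gzmf, which was not tested. The log2 ratio of Gzmf was -9.87. The value of -4.78 after thinning to 1000 UMIs is a bound from the floor of 3 counts, so it does not show a smaller difference. Oxsr1, a kinase gene on chromosome 9, stood higher in CD8 T-like cells (32.9 and 154 CPM) and in Treg-like cells (log2 3.77), where it was 0.085 with each library clustered alone. It was near equal in NK-like cells (10.2 and 11.2 CPM). Of the chromosome 11 genes Ccl5, Ccl3, Ccl4 and 1700020L24Rik, the last lies outside the chemokine cluster at 83437677 to 83441233 and stood higher with them in CD8 T-like cells (log2 2.64).

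Melanoma genes, from cells the CD45 sort should remove, were found almost only in control myeloid cells, at 229 and 27.4 CPM in monocyte- or macrophage-like cells and led by Dct and Mlana with 355 and 302 control UMIs against 5 and 5. In that class the list had a median of -2.86, which ran from -3.77 to -0.84 over the alternatives. Erythroid genes gave 248 and 0 UMIs over all cells, where 3 UMIs would be 0.342 CPM of the Nrp1L/L library, fibroblast genes 48 and 12 UMIs, and endothelial genes 24.4 and 77.6 CPM in monocyte- or macrophage-like cells. Dissociation stress genes had medians of 0.25 in monocyte- or macrophage-like, 0.26 in CD8 T-like, 0.54 in Treg-like and 0.64 in NK-like cells, and reached 7526 and 11803 CPM in NK-like cells. The labels do not record whether the tumours were handled side by side.

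The free RNA test of the interferon-gamma list was chosen only after its result was seen, while the other predictions here were written before theirs. Interferon-gamma response genes stood higher in the monocyte- or macrophage-like cells of the Nrp1L/L library. With each class's share of free RNA subtracted, the median stayed at 1.299 (1.10 to 1.37), against free RNA as the cause. With each of the 7 clusters given the same weight in both libraries, it was 0.83 (0.70 to 0.95), above the bound of 0.58 set beforehand, and all 7 clusters had a median above 0, from 0.28 to 1.40. A different mix of these 7 clusters may therefore account for part of the difference, but at these weights not for all of it. The clusters led by Cxcl3, Dct and Lpl held only 12, 15 and 12 Nrp1L/L cells, and the interval counts UMIs as independent. Cxcl10, Gbp2 and Cxcl9 help to lead the cluster with the most Nrp1L/L cells (78), so the mix is not separate from the response. The test cannot see a different mix of cell states within a cluster. More Ifng from lymphocytes of Nrp1L/L tumours is a hypothesis that remains open, as do the type I interferons, mouse, tumour and handling, since each library is 1 sample.

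Cholesterol synthesis genes stood lower in 4 classes, with a median over the class medians of -0.72 (-0.80 to -0.50). Cells matched on UMI number gave -0.52 (-0.70 to -0.33), past the bound of -0.3 set beforehand, which argues against the deeper control cells as the whole cause over the classes together. The matched class medians were -0.84 in monocyte- or macrophage-like, -0.52 in CD8 T-like, -0.52 in Treg-like and -0.25 in NK-like cells, so in NK-like cells, at -0.65 before matching, the value passed to the other side of the bound and depth stays open. Cycling cells make membranes and may account for part of it: without them the value was -0.61 (-0.68 to -0.24), an interval that spans the bound, so this test left it open. The 4 class medians without cycling cells ran from -0.63 in NK-like to -0.36 in Treg-like cells, the latter on 5 genes. SREBP1 targets had medians of -0.42 in monocyte- or macrophage-like, 0.00 in CD8 T-like, 0.59 in Treg-like (5 genes) and 0.46 in NK-like cells (7 genes). Whether these targets share the pattern was left open. Whether it follows genotype or library cannot be told apart.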
